A study of Mus musculus with 6 samples.

How the data were processed

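Gene expression was measured with Affymetrix arrays in total RNA from small intestinal crypts of mice on a C57BL/6 background. The crypts were released from the gut wall with EDTA after the villi had been scraped off, per the labels. Each of the 6 samples was hybridised to its own array. CSN8fl/fl mice carry a loxP-flanked Cops8 gene, which encodes subunit 8 of the COP9 signalosome, and CSN8ΔIEC mice were taken as mice lacking it in intestinal epithelial cells, as the name of the genotype says. Each genotype had 3 samples, which the labels call biological replicates without saying whether each came from a separate mouse. If some shared a mouse, the p-values measure only the spread between these samples, part of which may be technical. Replicates 1 and 2 of each genotype were labelled as females of 16 weeks and replicate 3 as a male of 10 weeks, so that labelled sex and age change together and are balanced over the genotypes.

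The deposited values are log2 probe set signals. The authors used RMA (background correction, quantile normalisation and summarisation of probes into probe sets) and Partek 6.6, per the submitters' processing notes. The settings and the genome build behind the array annotation are not given in the sources used here, and no genome coordinates are printed. The table held 22206 probe sets. Gene symbols came from the platform annotation: 19572 probe sets had 1 symbol, 0 had several and 2634 are unnamed here. All 19572 gene IDs matched the reference gene table used to check the symbols. For the 55 genes with more than 1 probe set, the probe set with the highest mean over the 6 samples was used, and for 0 of them did the probe sets disagree on the call. This left 19505 genes. Arrays have no read depth; the number of arrays limits the precision, and signals near the top of the range respond less to a change in RNA. The library medians differed by at most 0.058 on the log2 scale.

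Genotypes were compared with the moderated linear model of limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8.85 residual degrees of freedom after moderation), as CSN8ΔIEC minus CSN8fl/fl, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. Unless stated otherwise, adjusted p-values are from this fit, tests are two-sided, values of a group are means ± SD of log2 signals and differences are log2 differences ± SE. A further model with genotype and the labelled sex and age gave the difference between labelled males and labelled females, and another added their interaction. In that model, each genotype had 1 library labelled male, so the spread came from the labelled females alone.

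Before the data were examined, 42 gene lists were fixed. They were α-defensins, other Paneth cell antimicrobials, the union of these as Paneth cell antimicrobials, other epithelial antimicrobials, Paneth cell markers without antimicrobials, goblet cell, intestinal stem cell, enterocyte, enteroendocrine cell and tuft cell markers, Wnt target genes, the Notch pathway, proliferation, COP9 signalosome subunits, cullins and neddylation, proteasome subunits, NRF2 targets, HIF targets, NF-κB targets and acute inflammation, interferon-stimulated genes, MHC class II, autophagy and lysosome, the unfolded protein response and ATF4 targets, p53 targets, apoptosis and necroptosis, cholesterol synthesis, T cell and intraepithelial lymphocyte, B cell and plasma cell, myeloid cell, stromal and muscle, endothelial, and enteric nerve and glia markers, erythrocyte genes, pancreatic enzymes, proximal and distal small intestine genes, immediate-early and heat shock genes, circadian clock genes, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones and Y-linked genes. Lists with at least 3 measured members were tested, which left out the erythrocyte genes and the mitochondrially encoded genes. The Y-linked genes served as a check of the sex labels, and 39 lists were tested with limma's camera at its preset inter-gene correlation of 0.01. Camera compares a list with all other genes, and its p-values were adjusted over the 39 lists. Camera with a correlation estimated from the data, camera on ranks and fry were run beside it. Fry results are those of its directional test, unless its mixed test, which counts changes of members in either direction, is named. Of the lists' genes not measured by a probe set with a symbol, none was analysed here.

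The rule for the genes named in the text was fixed at the same time. It took Cops8; the 12 largest increases and the 12 largest decreases among genes past the threshold whose 3 CSN8ΔIEC values lay on one side of the 3 CSN8fl/fl values, without predicted genes, symbols of an accession kind, microRNAs and snoRNAs; up to 4 members of each list by smallest p, and 8 of the Paneth cell antimicrobials; the Y-linked genes and Xist; and the 5 genes with the smallest p for labelled sex and age and for the interaction. Genes of a family described among the other observations were chosen after their values were seen.

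The alternatives were a filter on dim probe sets (mean above 6.74, the median of all probe sets), a repeated quantile normalisation, centring each library on its median, the mean or the most variable probe set of a gene, an intensity trend with a robust prior, array weights, labelled sex and age as a covariate, the replicate number as a term, the labelled females alone, leaving out each library in turn, other thresholds, other list tests, and other ways of counting the α-defensins. The model was tested on simulated data in which 200 of 19505 genes were changed for the comparison of CSN8ΔIEC with CSN8fl/fl. It recovered 0% of them at a log2 step of 0.5, 76% at a step of 1 and 100% at a step of 2, with 0, 6 and 13 unchanged genes called. Each simulated run gave all changed genes the same step and drew the spread of each gene at random. Genes were drawn independently, while the correlation estimated from the data was 0.889 for α-defensins. No simulated library stood apart from the others, as CSN8fl/fl replicate 3 did. The shares recovered and the false calls may therefore differ in the real data. The simulation does not show whether a change of the size and spread seen for Cops8 could be recovered in the real data. Cops8 itself passed with dim probe sets filtered out (adjusted p = 0.0431). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.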

Results

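Crypt RNA from 3 CSN8fl/fl and 3 CSN8ΔIEC samples was compared to ask whether loss of CSN8 from the intestinal epithelium changes the production of antimicrobial peptides. CSN8, encoded by Cops8, is a subunit of the COP9 signalosome, a complex that removes the ubiquitin-like protein NEDD8 from cullin-RING ubiquitin ligases. Signals of the 19505 genes tested were read from 1 array per sample, and the number of arrays limits the precision. The labels call the samples biological replicates but do not say that each came from a separate mouse. Replicate 3 did not share a mouse with replicates 1 and 2, since the Y-linked gene Eif2s3y was at 4.06 against 9.95 and 10.1 in CSN8fl/fl and at 2.81 against 9.87 and 9.61 in CSN8ΔIEC. The p-values measure only the spread between these samples, part of which would be technical if replicates 1 and 2 shared a mouse. Pearson correlations across all probe sets lay between 0.976 and 0.993 for the 15 pairs of libraries. The library of CSN8fl/fl replicate 3 stood apart, with correlations of 0.976 to 0.986 with the other 5, and it lay at −42.3 on the first principal component against −8.06 and −13.3 for the other CSN8fl/fl libraries.

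The Cops8 signal (NCBI gene ID 108679) was lower in each CSN8ΔIEC library than in each CSN8fl/fl library. It was 8.26, 8.22 and 8.10 in CSN8fl/fl replicates 1 to 3 and 7.68, 7.61 and 7.77 in CSN8ΔIEC. The difference of −0.50 ± 0.11, or 1.42-fold, did not pass the threshold over all genes (adjusted p = 0.0865). It passed when dim probe sets were filtered out (adjusted p = 0.0431), and over all alternatives the adjusted p ranged from 0.0431 to 0.293. Whether the Cops8 probes lie within the deleted part of the gene is not given in the sources used here, and probes outside it do not check the genotype. None of the other 9 subunits measured passed the threshold. Gps1, which encodes subunit 1, had a difference of 0.38 ± 0.13 (adjusted p = 0.231), Cops5, the catalytic subunit, 0.24 ± 0.14 (adjusted p = 0.457) and Cops4 0.22 ± 0.12 (adjusted p = 0.452). Over the 10 subunits, 1, Cops8, passed when adjusted over the list alone (adjusted p = 0.0177). The differences of the other 9 were all above 0, but these 9 were not tested as a list without Cops8. The list of 10, with Cops8 in it, was not shifted (median 0.12, camera adjusted p = 0.184). The median was 0.067 and the Cops5 difference 0.15 without CSN8fl/fl replicate 3.

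Between genotypes, 210 genes changed, of which 73 rose and 137 fell in CSN8ΔIEC crypts, and 141 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 2918 genes. In 4365 genes, or 22.4%, the 3 values of one genotype all lay above those of the other, where chance gives 10%. The median difference over all genes was −0.011. The 12 largest increases included enzymes that act on carbonyls, esters, quinones and glutathione or glucuronide acceptors, besides Plet1, Il1rn and Slc1a3. Cbr3, a carbonyl reductase, rose 14.1-fold (log2 difference 3.82 ± 0.54, adjusted p = 0.0167), and Akr1b8, an aldo-keto reductase, rose from 7.90 ± 0.92 to 11.70 ± 0.29 (log2 difference 3.81 ± 0.39, adjusted p = 0.00581). The glutathione S-transferases Gsta3, Gsta2 and Gstm1 rose 13.4-, 3.58- and 3.56-fold, the carboxylesterases Ces1g and Ces1f rose 9.72- and 6.37-fold, the glucuronosyltransferase Ugt2b5 rose 5.57-fold and the quinone reductase Nqo1 rose 3.47-fold. Without CSN8ΔIEC replicate 1, Cbr3 (adjusted p = 0.0804), Gstm1 and Plet1 (adjusted p = 0.0601 for both) did not pass, and Gsta3, Ugt2b5, Gsta2, Slc1a3 and Nqo1 did not pass without that library or 1 to 3 others in turn, with adjusted p-values up to 0.105. The log2 differences of Cbr3 and Gsta3, 3.82 and 3.74 with all libraries, were 4.52 and 4.45 without CSN8fl/fl replicate 2, and Gsta3 rose 8.79-fold without CSN8fl/fl replicate 3. Plet1 rose 7.69-fold, the glutamate transporter Slc1a3 3.52-fold and Il1rn, which encodes the interleukin 1 receptor antagonist, 4.64-fold.

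The largest decreases included 4 gasdermin C genes. Gsdmc2 fell 12.6-fold from 12.14 ± 0.88 to 8.49 ± 0.89 (log2 difference −3.65 ± 0.50, adjusted p = 0.0148), and Gsdmc3, Gsdmc4 and Gsdmc fell 11.9-, 11.9- and 7.46-fold. Their sequences are related, and signal shared between them was not separated. Pnliprp2, a pancreatic lipase-related protein, and Clps, colipase, both among the Paneth cell markers, fell 9.59- and 8.62-fold. The tuft cell genes Rgs13, Siglecf and Dclk1 fell 9.04-, 8.69- and 6.58-fold. Fhl1 had the smallest adjusted p of the named decreases, with a 7.30-fold fall from 8.95 ± 0.18 to 6.08 ± 0.17 (adjusted p = 0.000194). Tspan6 fell 7.20-fold and the nucleoside transporter Slc28a1 6.47-fold. Rgs13 fell 5.92-fold, Siglecf 5.05-fold and Tspan6 4.62-fold without CSN8fl/fl replicate 3. The count of 210 genes moved by over 1.5 times without CSN8ΔIEC replicate 1 (41 genes), CSN8fl/fl replicate 2 (109), CSN8ΔIEC replicate 3 (114) or CSN8ΔIEC replicate 2 (122). Pnliprp2 and Dclk1 did not pass without CSN8ΔIEC replicate 1 (adjusted p = 0.0558 for both), and Gsdmc2, Rgs13, Siglecf, Gsdmc, Tspan6 and Slc28a1 did not pass without that library or 1 to 3 others in turn, with adjusted p-values up to 0.15. Of the 12 largest increases, Akr1b8, Ces1f, Ces1g and Il1rn passed the threshold without any 1 library, and of the 12 largest decreases Clps, Fhl1, Gsdmc3 and Gsdmc4 did.

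**Figure D1:**
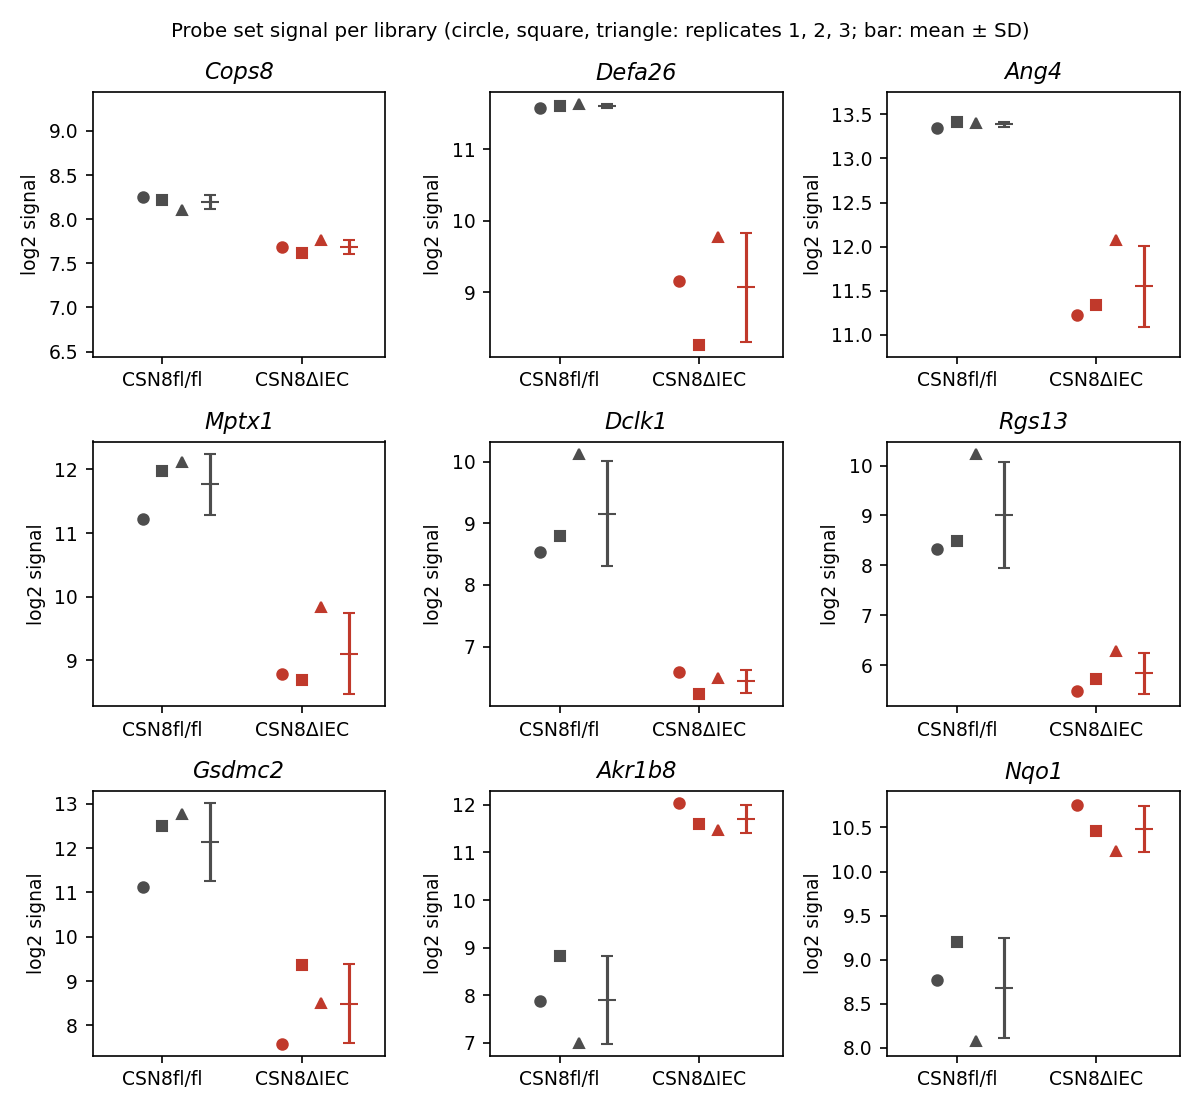
Log2 signal of 9 genes in the 3 CSN8fl/fl (grey) and 3 CSN8ΔIEC (red) libraries, with a bar for the mean ± SD of each genotype; each panel has its own range. Cops8 differed by −0.50, Defa26, Ang4, Mptx1, Dclk1, Rgs13 and Gsdmc2 were lower and Akr1b8 and Nqo1 higher in each CSN8ΔIEC library, and CSN8fl/fl replicate 3 (triangle) had the highest Dclk1 and Rgs13 signals.

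Antimicrobial genes of Paneth cells, the granule-bearing secretory cells at the crypt base, were lower in CSN8ΔIEC crypts. Of 30 genes measured, 7 fell and 0 rose, 25 fell when adjusted over the list alone, and 25 had all 3 CSN8ΔIEC values below all 3 CSN8fl/fl values. The median difference was −1.07 (camera adjusted p = 4.71e-22). With an estimated correlation the list did not pass (adjusted p = 0.395), nor did it with fry (adjusted p = 0.107). Ang4, an antibacterial angiogenin, fell 3.57-fold from 13.39 ± 0.030 to 11.55 ± 0.46 (log2 difference −1.84 ± 0.21, adjusted p = 0.0087). Mmp7, the protease that activates α-defensins in mice, fell 1.98-fold (adjusted p = 0.0294). The α-defensins Defa26, Defa40, Defa28, Defa30 and Defa31 fell 5.80-, 3.48-, 3.28-, 2.57- and 2.27-fold, with adjusted p-values from 0.00996 for Defa26 to 0.0465 for Defa31, and Defa27 differed by −1.02 (adjusted p = 0.057), which passed without CSN8ΔIEC replicate 3 (adjusted p = 0.0211; range over the alternatives 0.0138 to 0.232). Ang4 passed without any 1 library. Without CSN8ΔIEC replicate 1, Defa26 (adjusted p = 0.0514), Defa28 (which did not pass without CSN8ΔIEC replicate 2 either, adjusted p up to 0.0912), and Defa40, Defa30, Defa31 and Mmp7 did not pass. These last 4 did not pass without any 1 CSN8fl/fl library either, nor Defa31 and Mmp7 without CSN8ΔIEC replicate 2, with adjusted p-values up to 0.164. The count of 7 was 1 without CSN8ΔIEC replicate 1, 4 without CSN8ΔIEC replicate 2, 18 without CSN8ΔIEC replicate 3 and 3 without any 1 CSN8fl/fl library.

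All 22 α-defensins measured had lower signals in each CSN8ΔIEC library than in each CSN8fl/fl library, with differences from −0.73 to −2.54. Of them 5 fell over all genes and 22 when adjusted over the list alone; the 5 were 0, 3 and 16 without CSN8ΔIEC replicates 1, 2 and 3 and 2 without any 1 CSN8fl/fl library. The median was −1.17 (camera adjusted p = 4.71e-22, with an estimated correlation adjusted p = 0.395). The α-defensins are near-identical copies, and these 22 genes gave 19 distinct sets of values, so they are not independent measurements. In CSN8fl/fl crypts 13 of them had a mean above 13, where the highest signal in any library was 14.1. The 8 other antimicrobials had a median of −0.45, with 2 that fell, 0 that rose and 3 that fell when adjusted over the list alone (camera adjusted p = 0.00161, with an estimated correlation adjusted p = 0.502). Besides Ang4 and Mmp7, the lectin Itln1 differed by −0.67 ± 0.14 (adjusted p = 0.0703) and Lyz1, the Paneth cell lysozyme, by −0.51 ± 0.22 (adjusted p = 0.324), or −0.26 without CSN8ΔIEC replicate 2. The C-type lectins Reg3b and Reg3g differed by 0.095 and 0.18 (adjusted p = 0.843 and 0.733); they were chosen after their values were seen. Without CSN8fl/fl replicate 3, the median over the 30 antimicrobials was −1.16 and 3 of them fell. Of the 8 other antimicrobials, Ang4 and Mmp7 both fell without CSN8ΔIEC replicate 3, and Ang4 alone without each of the other libraries in turn. The other epithelial antimicrobials were not shifted, with 0 of 14 past the threshold over all genes, 2 that fell when adjusted over the list alone and a median of −0.14 (camera adjusted p = 0.145). Among them Duoxa2 differed by −1.62 (adjusted p = 0.0541), Defb1 by −2.12 (adjusted p = 0.119) and Retnlb by −2.47 (adjusted p = 0.188). Duoxa2 and Retnlb passed without CSN8fl/fl replicate 1 (adjusted p = 0.024 and 0.00274), where the Retnlb difference was −3.58. Defb1 passed without CSN8fl/fl replicate 3 (adjusted p = 0.029) with a smaller difference of −1.34, and that of Retnlb was −1.74 there.

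Paneth cell markers other than the antimicrobials were lower as well. Of 20 measured, 10 fell and 0 rose over all genes, 15 fell when adjusted over the list alone, and the median was −0.92 (camera adjusted p = 1.21e-13, with an estimated correlation adjusted p = 0.336). Besides Clps, Mptx1, a pentraxin, fell 6.35-fold (log2 difference −2.67 ± 0.33, adjusted p = 0.00996), Nupr1 fell 4.65-fold and Habp2 3.78-fold. Without CSN8ΔIEC replicate 1, Mptx1, Nupr1 and Habp2 did not pass (adjusted p = 0.0535 for each), and 1 of the 20 fell. Without CSN8fl/fl replicate 3 the list's median was −0.80 with 7 that fell, and 6 fell without CSN8fl/fl replicate 2 or CSN8ΔIEC replicate 2.

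**Figure D2:**
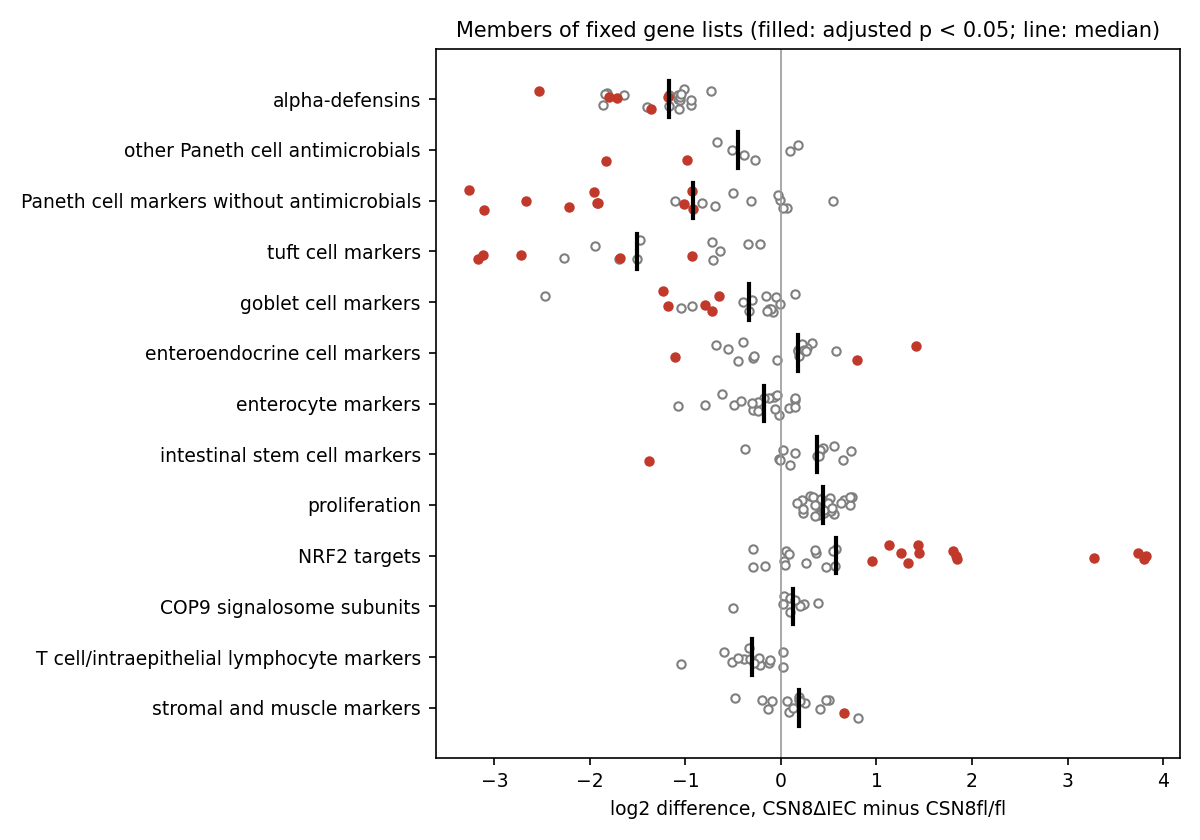
Log2 difference, CSN8ΔIEC minus CSN8fl/fl, of each measured member of 13 gene lists; filled points had an adjusted p under 0.05 over all genes and the black line is the list's median. The medians were −1.17 for α-defensins, −0.92 for the other Paneth cell markers, −1.51 for tuft cell markers and 0.58 for NRF2 targets.

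NRF2 targets, genes of the response to oxidants and electrophiles, were higher in CSN8ΔIEC crypts. Of 27 measured, 13 rose and 0 fell over all genes, 17 rose when adjusted over the list alone, and the median was 0.58 (camera adjusted p = 3.31e-17, with an estimated correlation adjusted p = 0.395). The 4 members with the smallest p were Akr1b8, Gstm1, Ces1g and Abcc3, an organic anion exporter that rose 2.19-fold (log2 difference 1.13 ± 0.15, adjusted p = 0.0148) but did not pass without CSN8ΔIEC replicate 1 or 3 (adjusted p up to 0.0717). Without any 1 library the median of the NRF2 targets stayed between 0.58 and 0.67, and with dim probe sets filtered out it was 0.96. The count of 13 that rose was 3 without CSN8ΔIEC replicate 1, 7 without CSN8ΔIEC replicate 2, 8 without CSN8ΔIEC replicate 3, 12 without CSN8fl/fl replicate 1 and 11 without CSN8fl/fl replicate 2 or 3. The lists of cullins and neddylation and of proteasome subunits had small upward medians of 0.094 and 0.14 with 0 of 26 and 0 of 30 members past the threshold, adjusted over all genes or over the list alone. Their camera adjusted p-values were 0.0442 and 0.00185, and with an estimated correlation the adjusted p-values were 0.722 and 0.745. Neither list passed without CSN8fl/fl replicate 3 (adjusted p = 0.246 and 0.337), and cullins and neddylation did not pass without CSN8ΔIEC replicate 1 or 2 either (adjusted p = 0.154 and 0.089; range over the alternatives 0.0124 to 0.246). The median of proteasome subunits was 0.038 without CSN8fl/fl replicate 3 and 0.23 without CSN8fl/fl replicate 2. Skp2 differed by 0.39, Cul7 by −0.41 and Psma3 by 0.35 (adjusted p = 0.267, 0.192 and 0.333), and Psma3 by 0.21 without CSN8fl/fl replicate 3.

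Markers of tuft cells, chemosensory cells of the epithelium, were lower in CSN8ΔIEC crypts. Of 15 measured, 5 fell and 0 rose over all genes, 13 fell when adjusted over the list alone, and the median was −1.51 (camera adjusted p = 2.02e-13, with an estimated correlation adjusted p = 0.395). Dclk1 fell from 9.16 ± 0.85 to 6.44 ± 0.19 (adjusted p = 0.0128) and Cd24a, also on the Paneth cell list, fell 1.91-fold, but passed only without CSN8fl/fl replicate 1 when libraries were left out in turn (adjusted p up to 0.124). The library of CSN8fl/fl replicate 3 had by far the highest tuft cell signals, with a median of 1.70 above each gene's mean over the 6 libraries against 0.31 and 0.33 in the other CSN8fl/fl libraries. Without it, the median difference was −1.01 and 7 of the 15 markers fell; 7 also fell without CSN8fl/fl replicate 1, 2 without CSN8fl/fl replicate 2, and 0, 1 and 2 without CSN8ΔIEC replicates 1, 2 and 3. Of the goblet cell markers 5 of 19 fell and 0 rose, 9 fell when adjusted over the list alone, and the median was −0.34 (camera adjusted p = 8.66e-08, with an estimated correlation adjusted p = 0.395). They included Clca1, a secreted mucus protein that fell 1.74-fold, the chemokines Ccl6 and Ccl9, which fell 2.35- and 2.27-fold, and the tryptase Tpsg1, which fell 1.65-fold. Without CSN8fl/fl replicate 3 the goblet cell median was −0.22 and 1 marker fell, as without CSN8fl/fl replicate 2, CSN8ΔIEC replicate 1 or CSN8ΔIEC replicate 2, and 3 fell without CSN8fl/fl replicate 1 or CSN8ΔIEC replicate 3. Ccl6 passed without any 1 library, Clca1 only without CSN8fl/fl replicate 1, Ccl9 only without CSN8ΔIEC replicate 3 and Tpsg1 did not pass once any 1 was left out (adjusted p up to 0.175). Enteroendocrine markers went both ways, with 2 of 19 that rose and 1 that fell over all genes, 2 that rose and 4 that fell when adjusted over the list alone, and no shift of the list (median 0.18, camera adjusted p = 0.754). Tac1, the substance P precursor, rose 2.66-fold and Cck 1.73-fold, and Sst, somatostatin, fell 2.15-fold; Gip differed by −0.69 (adjusted p = 0.0515). Tac1 passed without any 1 library, Sst did not without CSN8ΔIEC replicate 1 or 3 (adjusted p up to 0.0875), and Cck passed only without CSN8ΔIEC replicate 2 (adjusted p up to 0.198).

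Proliferation genes had higher signals in CSN8ΔIEC crypts as a list, with all 28 differences above 0 and a median of 0.44 (camera adjusted p = 5.39e-11, with an estimated correlation adjusted p = 0.561). None of the 28 passed over all genes, and 5 rose when adjusted over the list alone, among them Rrm2 (difference 0.74, adjusted p over all genes = 0.0684), Mcm3 (0.72), Hells (0.66) and Cdt1 (0.53). The median fell to 0.23 without CSN8fl/fl replicate 3, whose proliferation genes lay at −0.69 relative to the mean of the 6 libraries. Rrm2 passed without CSN8fl/fl replicate 1 (adjusted p = 0.0349). Intestinal stem cell markers had a median of 0.38, with 5 of 15 that rose and 2 that fell when adjusted over the list alone (camera adjusted p = 0.0424, with an estimated correlation adjusted p = 0.745). Over all genes 1 passed, Slc14a1, a urea transporter, which fell 2.61-fold (adjusted p = 0.00244); Ascl2, a stem cell transcription factor, differed by 0.73 (adjusted p = 0.0983). The stem cell list was not shifted without CSN8fl/fl replicate 3 (median 0.17, adjusted p = 0.383), CSN8ΔIEC replicate 1 (adjusted p = 0.0632) or CSN8ΔIEC replicate 3 (adjusted p = 0.228), and over the alternatives the adjusted p of intestinal stem cell markers ranged from 0.00364 to 0.912. Ascl2 passed without CSN8fl/fl replicate 1 (adjusted p = 0.0362). Wnt target genes had 0 of 12 past the threshold, 3 that rose over the list alone and a median of 0.19 (camera adjusted p = 0.0799). They passed without CSN8fl/fl replicate 1 or CSN8ΔIEC replicate 2 (adjusted p = 0.0326 and 0.0138; range over the alternatives 0.0138 to 0.912). Cd44 differed by 1.06 (adjusted p = 0.0604, and 0.0205 without CSN8ΔIEC replicate 2) and Myc by 0.76 (adjusted p = 0.195). The Notch pathway had 0 of 14 past the threshold and a median of 0.014 (camera adjusted p = 0.806).

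A further 6 lists passed camera at the preset correlation with 1 or 0 members past the threshold over all genes. Cytosolic ribosomal proteins had a median of 0.24 (adjusted p = 4.16e-09, with an estimated correlation adjusted p = 0.722), and replication-dependent histones had a median of 0.13 (adjusted p = 0.0424, with an estimated correlation adjusted p = 0.791) with 1 member that fell, H2bc21, by 1.63-fold. The 58 members of the histone list were taken by symbol. They included H13, which is not a histone, and the linker histones H1f7, H1f8 and H1f10, which are not replication-dependent. T cell and intraepithelial lymphocyte markers had a median of −0.30 (adjusted p = 0.00214, with an estimated correlation adjusted p = 0.722), and Ptprc, the pan-leukocyte gene, differed by −1.05 (adjusted p over all genes = 0.106). Distal small intestine genes had a median of −0.45 (adjusted p = 0.00616, with an estimated correlation adjusted p = 0.395), circadian clock genes one of −0.32 (adjusted p = 0.0243, with an estimated correlation adjusted p = 0.502) and enterocyte markers one of −0.17 (adjusted p = 0.0426, with an estimated correlation adjusted p = 0.783). Alpi, the intestinal alkaline phosphatase of enterocytes, differed by −1.08 (adjusted p over all genes = 0.0681, and 0.0413 without CSN8ΔIEC replicate 2). Adjusted over the list alone, 2 histones, 3 T cell, 2 distal, 2 clock and 1 enterocyte member fell, and 0 of the 60 ribosomal proteins passed. In CSN8fl/fl replicate 3 these lists lay at −0.39 for ribosomal proteins, −0.49 for histones, 0.54 for T cell markers, 0.31 for distal genes, 0.61 for clock genes and 0.34 for enterocyte markers, relative to the mean of the 6 libraries. Without that library the medians were 0.10, −0.099, −0.094, −0.30, −0.021 and −0.0086 in the same order, and the histone, T cell, clock and enterocyte lists did not pass (adjusted p = 0.0758, 0.222, 0.183 and 0.598). Enterocyte markers and replication-dependent histones did not pass without CSN8ΔIEC replicate 1 either (adjusted p = 0.149 and 0.343, medians −0.17 and 0.085), enterocyte markers without CSN8ΔIEC replicate 3 (adjusted p = 0.361, median −0.10) and circadian clock genes without CSN8fl/fl replicate 1 (adjusted p = 0.0698). Without CSN8fl/fl replicate 2 the medians were −0.30 for enterocyte markers, −0.47 for T cell and intraepithelial lymphocyte markers, −0.51 for circadian clock genes and 0.26 for replication-dependent histones, and without CSN8fl/fl replicate 1 the histone median was 0.21. H2bc21 passed only without CSN8fl/fl replicate 3 when libraries were left out (adjusted p up to 0.156). Over all genes, 2 histones fell without CSN8fl/fl replicate 3, 1 clock gene without CSN8fl/fl replicate 2, and 1 ribosomal and 1 enterocyte gene without CSN8ΔIEC replicate 2.

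The remaining lists were not shifted at the preset correlation. Over all genes, 1 of 16 stromal and muscle markers rose (Acta2, smooth muscle actin, 1.58-fold), 1 of 12 endothelial markers rose (Lyve1, 2.13-fold) and 1 of 9 proximal small intestine genes fell (Cybrd1, a duodenal ferric reductase, 2.19-fold). The medians were 0.19 for stromal, −0.084 for endothelial and −0.035 for proximal genes (camera adjusted p = 0.0552, 0.806 and 0.754). Adjusted over the list alone, 1 stromal gene rose and 1 fell, 2 endothelial genes rose, and 1 proximal gene rose and 1 fell. Lyve1 passed without any 1 library, Cybrd1 did not without CSN8ΔIEC replicate 1 or 2 (adjusted p up to 0.1), 1 proximal gene rose without CSN8ΔIEC replicate 2, and Acta2 did not pass once any 1 library was left out (adjusted p up to 0.157). Stromal and muscle markers passed camera without CSN8ΔIEC replicate 2 (adjusted p = 0.0237; range over the alternatives 0.0223 to 0.476). In the other lists 0 members passed over all genes. Of the interferon-stimulated genes, 7 of 29 rose when adjusted over the list alone, among them Igtp (difference 0.93), Gbp3 (1.17), Tap1 (0.62) and Psmb8 (0.45), with a median of 0.059 (camera adjusted p = 0.252). Of NF-κB targets and acute inflammation 2 of 26 rose over the list alone, Tnfrsf1b and Cxcl5 (median −0.032, camera adjusted p = 0.876), of p53 targets 1 of 18, Plk2, fell (median −0.15, adjusted p = 0.145; Plk2 itself passed over all genes without CSN8fl/fl replicate 1, adjusted p = 0.0322), of the unfolded protein response and ATF4 targets 1 of 23, Phgdh, rose (median 0.061, adjusted p = 0.867), and of pancreatic enzymes 1 of 14, Cela1, rose (median −0.0033, adjusted p = 0.754). No member passed over the list alone in the following lists. MHC class II genes had a median of −0.23 (camera adjusted p = 0.123), HIF targets −0.14 (0.144), B cell and plasma cell markers −0.12 (0.291), enteric nerve and glia markers −0.13 (0.294), and immediate-early and heat shock genes −0.091 (0.431). Autophagy and lysosome genes had a median of −0.071 (adjusted p = 0.219), apoptosis and necroptosis genes −0.060 (0.754), cholesterol synthesis genes 0.12 (0.528) and myeloid cell markers 0.052 (0.761). Some of these lists passed without 1 library: B cell and plasma cell markers without CSN8fl/fl replicate 3 (median −0.31, adjusted p = 0.00273), HIF targets without CSN8fl/fl replicate 1 or 2 (adjusted p = 0.042 and 0.0156), MHC class II without CSN8fl/fl replicate 2 or CSN8ΔIEC replicate 3 (0.0391 and 0.0406), p53 targets without CSN8fl/fl replicate 2 (0.0161), interferon-stimulated genes without CSN8ΔIEC replicate 1 (0.0444) and cholesterol synthesis without CSN8ΔIEC replicate 3 (0.0449). Without any 1 library, the medians of the lists that did not pass with all 6 lay between −0.33 for MHC class II and 0.27 for Wnt target genes. Over all genes, 2 B cell and plasma cell markers fell without CSN8fl/fl replicate 3, 1 HIF target fell without CSN8fl/fl replicate 2, and 1 immediate-early or heat shock gene rose without CSN8fl/fl replicate 1. Ripk3 and Mlkl, of the necroptosis pathway, differed by 0.58 and 0.52 (adjusted p = 0.136 and 0.158). The 1 erythrocyte gene measured, Alas2, differed by −0.32 (adjusted p = 0.286).

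In all, 17 of 39 lists were shifted at the preset correlation, 7 upward and 10 downward. Other splits of the 6 samples into 3 and 3 gave 6 to 19 lists at that setting. The correlation estimated from the data was 0.889 for α-defensins, 0.808 for tuft cell markers, 0.26 for NRF2 targets and 0.109 for Paneth cell markers without antimicrobials, against the preset 0.01. With an estimated correlation 0 passed when adjusted and 3 of the 17 passed unadjusted, and fry called 1 list, the Paneth cell markers without antimicrobials (adjusted p = 0.0393). Fry's mixed test, which does not ask for a common direction, called 16 of the 39 lists. Among them were Paneth cell antimicrobials (adjusted p = 0.0271), tuft cell markers (0.0387) and NRF2 targets (0.00482). Enteroendocrine and endothelial markers, not shifted with camera, were among them too (0.003 for both). At the preset correlation without CSN8fl/fl replicate 3, 11 lists were shifted, 10 of them among the 17.

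The sex labels went against the Y-linked genes in all 6 libraries. The libraries labelled female had high signals of Eif2s3y (9.88 ± 0.21), Kdm5d (7.66 ± 0.20) and Uty (8.73 ± 0.18, SD, n = 4). In the CSN8fl/fl and CSN8ΔIEC libraries labelled male, Eif2s3y was at 4.06 and 2.81, Kdm5d at 3.62 and 3.29 and Uty at 3.30 and 3.21. Ddx3y and Xist were not analysed here. Between the libraries labelled male and those labelled female, limma called 3 genes, and these were the 3 Y-linked genes, with differences of −6.45, −4.20 and −5.48; 1202 genes had an unadjusted p under 0.05. The next smallest adjusted p was 0.723, and Gm20871, Gpm6a, Olfr1284, Acot1 and Zfp600 led the other genes with differences of −0.79, 0.97, 0.81, 0.82 and 0.94. Without CSN8ΔIEC replicate 3 the only library labelled male was CSN8fl/fl replicate 3, which stood apart. That fit sets this library alone against the labelled females, and its calls are not read here.

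**Figure D3:**
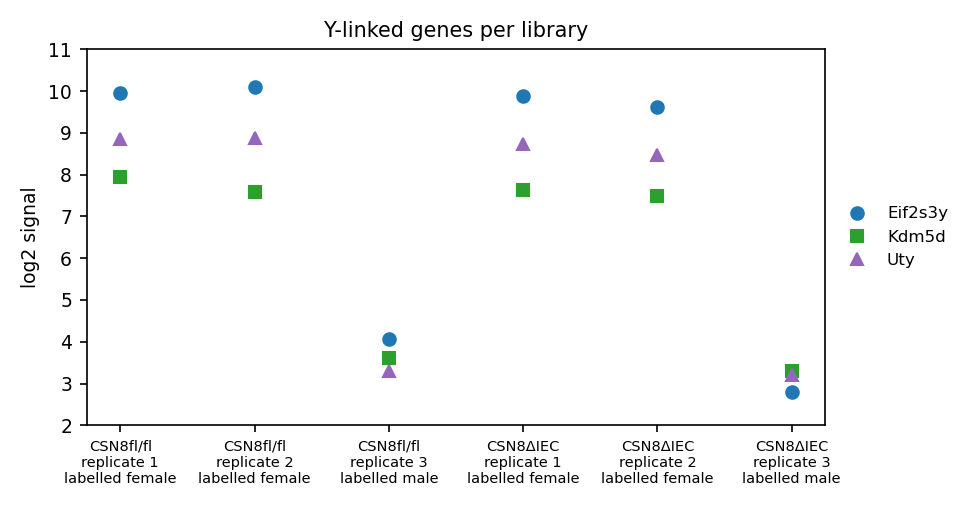
Log2 signal of the 3 Y-linked genes measured in each of the 6 libraries, with the sex given by the label. The 4 libraries labelled female lie between 7.50 and 10.1 and the 2 labelled male at 4.06 or below.

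For the question whether the genotype difference depended on labelled sex and age, limma called 0 genes, with 1974 at an unadjusted p under 0.05; with an intensity trend and robust prior it called 1. The smallest adjusted p was 0.232, shared by Il18r1, Ceacam18, Chrm4, Gnat3 and Lpar3. Gnat3, the taste G protein subunit gustducin of tuft cells, differed between genotypes by −1.03 in the labelled females and by −3.79 in the labelled males, and Il18r1, an interleukin 18 receptor chain, by 0.094 and −3.31. The labelled males were 1 library per genotype, and CSN8fl/fl replicate 3, which stood apart, was one of them.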

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

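The tests of the explanations weighed here were chosen after the results were seen; the splits of the samples and the interaction fit were planned. At camera's preset correlation, the genotype difference of 15 gene lists in the libraries labelled male differed from that in the libraries labelled female. With an estimated correlation 0 of them passed when adjusted, and the smallest adjusted p was 0.406. The median of the difference, labelled males minus labelled females, was 1.07 for α-defensins, 0.713 for other Paneth cell antimicrobials, 0.817 for all Paneth cell antimicrobials, 0.618 for stem cell markers, 0.708 for Wnt target genes, 0.676 for proliferation, −0.575 for enterocyte markers, −1.15 for tuft cell markers, 0.235 for proteasome subunits, −0.491 for HIF targets, −0.581 for T cell and intraepithelial lymphocyte markers, 0.729 for B cell and plasma cell markers, −0.673 for circadian clock genes, 0.47 for ribosomal proteins and 0.576 for histones. Each genotype had 1 library labelled male, so such a difference can come from CSN8fl/fl replicate 3 or CSN8ΔIEC replicate 3 alone. Among the probe sets unnamed here, 15 differed between genotypes at an adjusted p under 0.05 in a limma fit of all probe sets; 8 were higher and 7 lower in CSN8ΔIEC crypts, with differences from −3.50 to 2.27.

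Paneth cell antimicrobials were lower in CSN8ΔIEC crypts with camera at its preset correlation, but did not pass with an estimated correlation (adjusted p = 0.395) or with fry (adjusted p = 0.107). Probe sequence shared among the α-defensins does not account for the falls of Ang4 and Mmp7, which are not α-defensins. The antimicrobial median of −1.07 was −0.45 without the α-defensins and −0.51 with them counted as 1 member, so they carry much of its size. The 8 other antimicrobials, of which 2 fell, did not pass as a list with an estimated correlation (adjusted p = 0.502). How far shared sequence adds to the fall of the α-defensins themselves was not tested. The Paneth cell markers without antimicrobials, genes outside that list, had a median of −0.925 with 10 of 20 that fell (1 without CSN8ΔIEC replicate 1, where the median was −0.88). With an estimated correlation that list of markers did not pass either (adjusted p = 0.336). A lower share of crypts in the CSN8ΔIEC libraries would by itself lower stem cell and proliferation genes too. These 43 genes had a median of 0.407 (SD 0.352 over genes), and 0.209 without CSN8fl/fl replicate 3. Of them 28 were proliferation genes, and a rise of these with genotype could hide such a fall. The stem cell list was not shifted without CSN8fl/fl replicate 3 (camera adjusted p = 0.383). A lower share of crypts is therefore not excluded. Without CSN8fl/fl replicate 3 the antimicrobial median was −1.16. That library had the lowest antimicrobial signals of the CSN8fl/fl libraries, with a median of 0.49 above each gene's mean against 0.643 and 0.543. Leaving it out could thus hardly make the fall smaller. With each library left out in turn the median lay between −1.38 and −0.81, and it was −0.81 without CSN8ΔIEC replicate 2. A smaller number of Paneth cells and a lower expression in each of them may both give such values, and neither was tested. Distal small intestine genes were lower too (median −0.45, camera adjusted p = 0.00616, with an estimated correlation 0.395), with 0 of 8 past the threshold over all genes. Proximal genes were not shifted (median −0.035). Whether the libraries held unlike shares of proximal and distal gut was not tested.

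Tuft cell markers were lower in CSN8ΔIEC crypts with camera at its preset correlation, with the highest signals in CSN8fl/fl replicate 3, but did not pass with an estimated correlation (adjusted p = 0.395) or with fry (adjusted p = 0.11). Of the 15 markers 5 fell, against 2 without CSN8fl/fl replicate 2 and 0, 1 and 2 without CSN8ΔIEC replicates 1, 2 and 3. The median was −1.01 without CSN8fl/fl replicate 3, and 7 fell. Of the 15 markers, 12 were lower in each CSN8ΔIEC library than in both remaining CSN8fl/fl libraries. The lower values were thus not confined to the comparison with that library, although it adds to their size. The estimated correlation of the markers was 0.808, so they are not independent measurements, and how often chance gives such an order was not tested. Leaving that library out also leaves no CSN8fl/fl library with the labelled sex and age of CSN8ΔIEC replicate 3. A lower share of all rarer secretory cells would also lower enteroendocrine markers, whose median was 0.177 (SD 0.572 over genes). These markers went both ways, with 2 that rose and 4 that fell when adjusted over the list alone, so their median cannot tell the share of these cells. Goblet cell markers and Paneth cell markers without antimicrobials were lower too, with medians of −0.34 and −0.92. This explanation is therefore left open. Fewer tuft cells in CSN8ΔIEC crypts and a lower expression in each of them may both give such values, and neither was tested.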

How the results depend on the processing

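The alternatives were planned, except those that count identical probe sets once or count the members of lists and families past the threshold without each library, which were chosen after seeing the data. The count of 210 genes stayed within 1.5 times (202 to 298) under other filters on dim probe sets, normalisations, probe set choices, variance models and covariates, and was 141 with a 2-fold limit, 204 over all probe sets and 210 with identical probe sets once. It was 473 at an adjusted p under 0.1, 850 at an unadjusted p under 0.05 with at least 1.5-fold, and 97 in the labelled females alone (21.6% of them rose, against 34.8%). Leaving out 1 library gave 41 to 228 genes, 11 to 20 lists and 3 to 18 genes for labelled sex and age, the last 18 without CSN8ΔIEC replicate 3. The interaction called 1 gene with an intensity trend and robust prior and 0 under the other alternatives in which it could be fitted; it could not be fitted without either library labelled male. The Cops8 difference of −0.50 passed only with dim probe sets filtered out (adjusted p = 0.0431), where fewer genes were tested.

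The Paneth cell antimicrobials kept a median below 0 under every alternative run (−0.45 without the α-defensins to −1.43 in the labelled females alone), but their median of −1.07 did not pass with camera's estimated correlation (adjusted p = 0.395) or fry (0.107). These called 0 and 1 of the 39 lists, against 17 at the preset correlation, and the labelled females alone gave 11. The deviations gave no clear sign that the replicate numbers pair the samples. Those of same-numbered samples correlated at 0.117, −0.0243 and 0.0381, and 3 of 6 samples correlated best with their own number. So few samples cannot exclude a pairing, and replicate 3 of both genotypes shared its labelled sex and age. With the replicate block 202 genes were called, 159 of them among the 210.

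Of the named genes 1 and of the lists 13 changed direction somewhere; the cause was not tested. In the labelled females alone the medians were 0.0037 for enterocyte markers and −0.041 for histones, both called with all libraries, and −0.084 for Wnt targets, −0.028 for Notch, 0.041 for HIF targets, 0.0022 for apoptosis, 0.076 for pancreatic enzymes and 0.053 for proximal genes. With dim probe sets filtered out they were −0.0081 for Notch, −0.10 for interferon-stimulated genes and −0.48 for myeloid markers. Repeated quantile normalisation gave −0.00059 for Notch, 0.012 for NF-κB targets and 0.022 for pancreatic enzymes, centring 0.00014 and 0.029 for the last 2, and array weights −0.0020 for Notch, −0.0039 for the unfolded protein response and 0.018 for pancreatic enzymes. Without 1 library the medians ranged from −0.0045 to 0.27 for Wnt targets, −0.062 to 0.051 for Notch, −0.11 to 0.086 for interferon-stimulated genes, −0.014 to 0.21 for cholesterol synthesis, −0.031 to 0.14 for myeloid markers, −0.033 to 0.092 for pancreatic enzymes, −0.14 to 0.011 for proximal genes and −0.099 to 0.26 for histones, and the difference of the trypsin gene Prss1 from −0.0044 to 0.32. Over genes and alternatives, 2670 differences kept direction and side of the threshold, 198 lost and 54 gained a call; over lists other than the Paneth cell antimicrobials, with camera at the preset correlation, 523 kept both, 35 lost a call, 3 of them with a change of direction, and 15 gained one. Among the left-out libraries, most gene calls were lost without CSN8ΔIEC replicate 1 (45) and most list calls without CSN8fl/fl replicate 3 (7).

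The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 210 genes against at most 0 in the others (1 split as large), an antimicrobial median of size 1.07 against at most 0.733 (1 split), and 17 lists against 6 to 19 (2 splits). The 19 came from CSN8fl/fl 1 and 3 with CSN8ΔIEC 3 against the rest. Lists thus passed camera at the preset correlation in every split, also where 0 genes were called. The count of 17 lists does not by itself set the genotypes apart.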

Other observations

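Gene families, some with members on the fixed lists, were chosen after their values were seen, and the tests of the sex labels below, except that of the X-linked copies, were too. Of 7 Ugt2b glucuronosyltransferases 4 rose in CSN8ΔIEC crypts and 0 fell, with Ugt2b38 up 2.93-fold and Ugt2b35 2.66-fold besides Ugt2b5. Of 7 mu-class glutathione S-transferases 5 rose, among them Gstm4 2.76-fold and Gstm2 2.43-fold, and of 14 aldo-keto reductases 4 rose, among them Akr1c19 3.35-fold and Akr1c13 2.12-fold. All 3 alpha-class glutathione S-transferases measured rose. Without CSN8ΔIEC replicate 1 these counts were 2 for Ugt2b, 1 for the mu class, 2 for aldo-keto reductases and 0 for the alpha class. They were 2, 2, 4 and 1 without CSN8ΔIEC replicate 2, 4, 3, 4 and 1 without CSN8ΔIEC replicate 3, and 3, 3, 4 and 2 without CSN8fl/fl replicate 3. The other 10 aldo-keto reductases did not pass; Akr1c14 among them differed by −1.27 (adjusted p = 0.0829). Ugt2b38, Ugt2b35, Gstm2 and Akr1c19 passed without any 1 library, Akr1c13 did not without CSN8ΔIEC replicate 1 (adjusted p = 0.0529), and Gstm4 did not without CSN8fl/fl replicate 3, CSN8ΔIEC replicate 1 or CSN8ΔIEC replicate 2 (adjusted p up to 0.123). The carboxylesterase 1 genes went both ways, since Ces1c fell 2.57-fold while Ces1g and Ces1f rose and the other 4 did not pass; Ces1c passed only without CSN8fl/fl replicate 1 or 3 when libraries were left out (adjusted p up to 0.139). Signal shared between related members was not separated.

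Of 6 gasdermin C genes 4 fell, and the other 2, Gsdmcl1 and Gsdmcl2, had signals of 4.67 and 4.14 in CSN8fl/fl crypts. The count was 2 without CSN8fl/fl replicate 2, CSN8ΔIEC replicate 1 or CSN8ΔIEC replicate 3. Of 4 angiogenins 3 fell, Ang5 by 4.18-fold and Ang2 by 2.70-fold besides Ang4, and Ang6 differed by −0.87 (adjusted p = 0.129). Ang5 passed without any 1 library and Ang2 only without CSN8fl/fl replicate 1 (adjusted p up to 0.175). Armcx3, of the armadillo repeat X-linked family, fell 4.97-fold (adjusted p = 0.00298), and Tceal8 fell 2.11-fold (adjusted p = 0.0495, not past the threshold without 5 of the 6 libraries in turn, with an adjusted p up to 0.188), while the other 10 of these 12 genes did not pass. Of 13 small proline-rich and 18 Ms4a genes 0 passed the threshold over all genes, and 1 Ms4a gene fell without CSN8fl/fl replicate 3.

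The Y-linked signals were high in the 4 libraries labelled female and low in the 2 labelled male. Signal from the X-linked copies does not explain this, since Kdm5c, Kdm6a and Eif2s3x were not lower in the libraries labelled male. They differed there by 0.29, 0.45 and 0.14 on average (limma adjusted p = 0.782, 0.778 and 0.83). The Kdm5c and Kdm6a differences came mostly from CSN8fl/fl replicate 3 (9.585 and 10.71), with 8.988 and 10.02 in CSN8ΔIEC replicate 3. The Y-linked genes separated the libraries completely, with a gap of at least 3.87 between the lowest library labelled female and the highest labelled male. By these genes, replicates 1 and 2 of both genotypes held RNA from males, against their labels, while replicate 3 had low Y-linked signals, as from females. How the labels came to differ was not tested, and an exchange of the sex labels in both genotypes is a candidate explanation. The data do not show whether the age labels were exchanged with them, and the genotype model without labelled sex and age as terms uses neither label.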
